A study of Mus musculus with 12 samples.

How the data were processed

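RNA of LSK cells from 4 groups of male DBA2/J mice was measured on Agilent mouse arrays with 1 dye (Cy5), 3 arrays per group and 12 in all. Per the labels, the RNA was amplified with the WTA2 kit before labelling with Kreatech ULS. The deposited scanner output holds the red processed signal of every spot, an intensity. Per the file headers, the authors extracted it with Agilent Feature Extraction 11.5.1.1, which subtracted background, removed spatial and multiplicative trends within the array and put surrogate values in place of very low spots, without scaling between arrays. The scanner output also gives the raw mean and local background intensities per spot and flags for spots above background, saturated or outlying. A second deposited table holds the authors' normalized intensity values, on a linear scale, for 30354 probes. Its medians of 938 to 945 were nearly equal across arrays, as after quantile normalization, its log values had correlations of 0.998 to 1.00 with the processed signal, and its tool and its choice of probes were not stated.

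The labels' protocols mention treatments that no sample has, so groups were taken from each sample's own label. Each slide held 1 array of every group with the same replicate number. After group means were removed, the 18 pairs of same-numbered arrays had a Pearson r across genes of 0.260 to 0.616 (median 0.440), against a median of -0.240 for the 36 other pairs. Slide and replicate are thus the same factor, and a fit with the slide as a block is given beside each count. The labels do not say that the arrays of a group came from separate mice, so p-values measure only the spread between these samples.

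Of 43020 spots that were not controls, outlier spots were left out and replicate spots averaged on the log2 scale, giving 39429 probes; 0 were saturated. The log2 processed signal minus the array's 75th percentile was analysed. Probes above background on all arrays of at least 1 group were kept (29495), and 146 more were dropped because an array had only outlier spots. Gene names came from the scanner output, brought up to date for 28330 probes whose accession matched the gene table (GRCm38.p6), for 31131 names. Each gene was represented by its probe with the highest mean over all arrays, leaving 23793 genes. Positions are those of the scanner output in mm9, printed only for entries written in that assembly's form; no exon annotation of that assembly was at hand. Of 15371 genes with a position, 414 had a probe on another chromosome than the gene table gives.

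A linear model with 1 mean per group was fitted to all arrays with limma 3.58.1 (lmFit and eBayes; R 4.3.3, with version 1.17.8 of data.table; 8 residual and 3.82 prior degrees of freedom). The moderated tests were 2-sided and p-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison. Genes with an adjusted p under 0.05 passed. The 6 pairwise comparisons, the mean of the blood groups against marrow and a moderated F-test over the blood groups were run. The 18 gene lists and 8 cell type marker lists (544 entries, 513 distinct genes, 31 in more than 1 list) were tested with camera at a preset correlation of 0.01 and adjusted over the 26 lists of a comparison; counts adjusted over the list alone use the same gene p-values. A list needed 5 measured members. Lists, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined.

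The rule named, among genes that passed, had the same sign on all 3 slides, were above background on every array compared and had a proper symbol, the 8 largest increases and 8 largest decreases per comparison with marrow, and 5 and 5 in the other comparisons. It also named the 3 largest bounds each way among genes above background on 3 arrays of one group and 0 of the other. Such a bound sets each unseen value at the lowest signal above background of its array, or at its own signal if that was higher. Blnk, Cd5, H2-Aa, H2-Eb1, Nr4a3 and Tnfaip3 have fold changes against a group with 2 of 3 arrays above background. Up to 4 members of each described list with the smallest p were added, and Cxcr4, Cxcr2, Itga4, Itgb1, Csf3r, Kit and Ly6a were given in every comparison. Genes outside the rule are named in the shared calls and the closing part, chosen after their values were seen.

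The alternatives were quantile normalization, normexp background correction (offset 50), the authors' table, no filter on dim probes, only probes above background on all arrays, the slide as a block, an intensity trend with a robust prior, a fold change of at least 2, only the groups compared, every probe or the mean of a gene's probes, an estimated correlation or the fry test for lists, and leaving out each array in turn. Quantile normalization or a correction for probe GC content, each joined with the slide block, was added after the data were seen. The procedure was tested on simulated data for G-CSF against marrow (23793 genes): at log2 sizes of 1, 2 and 3 it recovered 2 of 69, 42 of 65 and 61 of 66 changed genes, and it called 1 of 23565 unchanged genes.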

Results

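Gene expression was measured in LSK cells, the lineage-negative Sca-1 and Kit positive fraction that holds the stem and early progenitor cells of the blood, sorted from male DBA2/J mice. Each of the 4 groups had 3 arrays. Marrow cells came from mice given PBS, and the other LSK cells came from the peripheral blood of mice given 1 of 3 mobilizing treatments. These were G-CSF, the growth factor of granulocytes, over 5 days in 9 injections; AMD3100 (plerixafor), a CXCR4 antagonist, for 1 hour; and CWHM-823, a VLA-4 inhibitor, given with tGro-b, a truncated CXCR2 agonist. The treatment times differ, and no time was given for the third. No blood of untreated mice was on the arrays, so every difference from marrow joins treatment and tissue. Signal at the 75th percentile ran from 1146 to 2724 across the 12 arrays. Between 70.7 and 83.3% of probes were well above background. With 3 arrays per group, the number of arrays limits the precision. Marrow array 3 stood apart in neutrophil transcripts: the median of 7 abundant neutrophil genes was 2.01 log2 units over the array's 75th percentile, against -2.52 and -2.53 on the other marrow arrays and -3.37 to -1.48 on the blood arrays. Counts without that array are given beside each comparison with marrow.

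The first comparison asks how LSK cells mobilized by G-CSF differ from those resident in marrow. Selp, the adhesion receptor P-selectin, was 30.8-fold higher in blood (log2 fold change 4.95 ± 0.26, adjusted p = 4.59e-06; ± gives the standard error, n = 3 arrays per group). Klf2, a transcription factor of lymphocyte trafficking, was 30.4-fold higher (4.93 ± 0.43, adjusted p = 9.53e-05), and Egr3, an immediate early transcription factor, 22.5-fold (4.49 ± 0.39, adjusted p = 9.17e-05). Socs3, the feedback inhibitor of STAT3 signalling, rose by 4.42 ± 0.32 (adjusted p = 3.29e-05). Lower in blood were the erythroid genes Klf1, a transcription factor (-2.24 ± 0.49, adjusted p = 0.0446), and Car1, a carbonic anhydrase (-2.79 ± 0.51, adjusted p = 0.0175), and Cd74, the invariant chain of MHC class II (-2.30 ± 0.44, adjusted p = 0.0218). The probes of Egr3 and Selp map in the mm9 mouse assembly to chromosome 14, 70479222 to 70479281, and chromosome 1, 166079660 to 166079719.

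In all, 413 of 23793 genes passed, 281 higher and 132 lower. With the slide as a block, 4646 passed, 1961 higher and 2685 lower; values called blocked come from that fit. The other genes with the largest increases were Trib1, Col18a1, Lmna and Pmaip1 (4.02 to 4.74, adjusted p = 4.59e-06 to 3.29e-05). Mn1, Igf2r, Pf4 (platelet factor 4), Neil3 and Slit2 had the largest decreases beside Klf1, Car1 and Cd74 (-2.87 to -2.11, adjusted p = 0.00177 to 0.0314). Each gene named here as changed moved the same way on all 3 slides. Gzmb, a granule protease, was above background on 3 G-CSF arrays and 0 marrow arrays and so was at least 17.4-fold higher (adjusted p = 3.35e-05). By the same reading the transcription factor Cebpd was at least 13.6-fold and Cd200r4 at least 10.1-fold higher. Tas2r130, Ddx4 and Rhag, an erythroid membrane protein, were above background only on marrow arrays among these 6, at least 8.65-fold, 6.80-fold and 3.71-fold lower. Of the receptor genes fixed for every comparison, Ly6a, which encodes Sca-1 (1.65 ± 0.33, adjusted p = 0.0308), and Itgb1, the beta chain of VLA-4 (1.42 ± 0.29, adjusted p = 0.0314), rose. Cxcr4 (-0.54 ± 0.27, adjusted p = 0.280), Cxcr2 (0.44 ± 0.28, adjusted p = 0.367), Itga4 (-0.06 ± 0.31, adjusted p = 0.914) and Kit (-0.17 ± 0.23, adjusted p = 0.649) did not pass. The probe for Csf3r, the G-CSF receptor gene, gave -0.63 ± 0.24, adjusted p = 0.192, 0.0329 blocked. It is placed on another chromosome, so no single value is taken as the receptor's level.

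Among the gene lists, the immediate early genes, induced within minutes of a stimulus, rose most (median 1.78, adjusted p = 2.52e-24; medians are of log2 fold changes). In that list 14 of 30 measured members rose, 0 fell and 16 did not pass (22 rose and 1 fell adjusted over the list alone, 22 and 1 blocked). Nr4a1 (3.57 ± 0.38), Atf3 (3.65 ± 0.41) and Klf6 (2.67 ± 0.27) were among the risen members. Of NF-kB target and inflammatory genes 4 of 25 measured members rose, 0 fell and 21 did not pass (7 rose and 0 fell adjusted over the list alone, 11 and 1 blocked), led by Bcl3 (3.25 ± 0.23), Tnf (3.03 ± 0.35) and Tnfaip3 (2.81 ± 0.39), with a median 0.64, adjusted p = 2.65e-07. The G-CSF and STAT3 response list rose (median 0.75, adjusted p = 4.12e-09). Its members Junb (2.92 ± 0.40), Pim1 (1.97 ± 0.27) and Pim2 (1.80 ± 0.27) were higher, and 9 of 21 measured members rose, 0 fell and 12 did not pass (10 rose and 2 fell adjusted over the list alone, 10 and 1 blocked). Myeloid priming genes, of granulocyte and monocyte progenitors, rose (median 0.50, adjusted p = 1.91e-05). Here 3 of 19 measured members rose, 0 fell and 16 did not pass (6 rose and 0 fell adjusted over the list alone, 7 and 0 blocked). Among them were the granule protease genes Ctsg (2.33 ± 0.31) and Prtn3 (1.89 ± 0.27) and also Ms4a3 (3.79 ± 0.65). Cholesterol synthesis genes rose as a list (median 0.87, adjusted p = 4.58e-10). Here 2 of 23 measured members rose, 0 fell and 21 did not pass (10 rose and 0 fell adjusted over the list alone, 11 and 0 blocked).

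A further 7 lists rose, but not with an estimated correlation. Adhesion and homing genes (median 0.25, adjusted p = 1.42e-05, adjusted p = 0.0535 with an estimated correlation; 4 up and 0 down of 32, 8 and 0 adjusted over the list alone, 11 and 0 blocked) included Cd9 (2.05 ± 0.32) and Itgb7 (1.25 ± 0.25). The mast cell and basophil markers (median 0.65, adjusted p = 0.00623, adjusted p = 0.0535 with an estimated correlation; 3 up and 0 down of 10, 4 and 0 adjusted over the list alone, 4 and 1 blocked) included Hdc, which makes histamine (2.76 ± 0.42), and Cpa3 (1.82 ± 0.29). Quiescence and CDK inhibitor genes (median 0.36, adjusted p = 0.000241, adjusted p = 0.205 with an estimated correlation; 5 up and 0 down of 20, 6 and 1 adjusted over the list alone, 7 and 1 blocked) were led by Nr4a1 and Klf4 (2.21 ± 0.34), which are also immediate early genes, and by Cdkn1a, the CDK inhibitor p21 (1.73 ± 0.31). Heat shock and stress genes (median 0.41, adjusted p = 2.21e-05, adjusted p = 0.0748 with an estimated correlation; 2 up and 0 down of 21, 7 and 0 adjusted over the list alone, 9 and 1 blocked) included Xbp1 of the unfolded protein response (1.60 ± 0.26). The respiratory chain genes of oxidative phosphorylation (median 0.77, adjusted p = 8.22e-15, adjusted p = 0.0991 with an estimated correlation; 1 up and 0 down of 30, 11 and 0 adjusted over the list alone, 18 and 0 blocked) had small single-gene changes. Hypoxia and glycolysis genes had 0 up and 0 down of 26, 5 and 0 adjusted over the list alone, 10 and 0 blocked (median 0.41, adjusted p = 2.64e-05, adjusted p = 0.242 with an estimated correlation). Ribosome biogenesis and MYC genes had 0 up and 0 down of 25, 0 and 0 adjusted over the list alone, 3 and 0 blocked (median 0.28, adjusted p = 0.000773, adjusted p = 0.249 with an estimated correlation).

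Dendritic cell markers fell (median -0.45, adjusted p = 0.000880). Here 0 of 11 measured members rose, 3 fell and 8 did not pass (0 rose and 4 fell adjusted over the list alone, 0 and 5 blocked): the MHC class II genes H2-Aa (-4.60 ± 0.52) and H2-Eb1 (-3.17 ± 0.66), and Cd74. Genes of mitosis (median -0.73, adjusted p = 1.11e-05, adjusted p = 0.0856 with an estimated correlation; 0 up and 2 down of 28, 0 and 5 adjusted over the list alone, 0 and 10 blocked) included Nusap1 (-1.27 ± 0.24) and Kif23 (-1.39 ± 0.31). Stem cell genes of the HSC list (median -0.44, adjusted p = 0.0161, adjusted p = 0.377 with an estimated correlation; 0 up and 3 down of 29, 1 and 8 adjusted over the list alone, 1 and 10 blocked) included the transcription factor Hlf (-1.19 ± 0.23), Mmrn1 (-1.52 ± 0.30) and Mllt3 (-0.95 ± 0.21). Lymphoid priming genes (median -0.62, adjusted p = 0.0155, adjusted p = 0.140 with an estimated correlation; 1 up and 2 down of 22, 1 and 6 adjusted over the list alone, 2 and 8 blocked) included the chemokine receptor gene Ccr9 (-1.64 ± 0.29). Neutrophil markers stood lower (median -1.33, adjusted p = 0.0446, 0.118 blocked, adjusted p = 0.416 with an estimated correlation; 0 up and 0 down of 10, 0 and 0 adjusted over the list alone, 0 and 1 blocked, 0.376 without marrow array 3). The remaining 9 lists did not pass. Megakaryocyte and platelet genes had 2 up and 1 down of 18, 2 and 4 adjusted over the list alone, 2 and 6 blocked (median -0.53, adjusted p = 0.465). Erythroid genes had 2 up and 3 down of 21, 3 and 8 adjusted over the list alone, 3 and 8 blocked (median -0.63, adjusted p = 0.379). DNA replication had 0 up and 0 down of 29, 0 and 0 adjusted over the list alone, 0 and 1 blocked (median 0.15, adjusted p = 0.190). Interferon response had 0 up and 0 down of 35, 2 and 1 adjusted over the list alone, 4 and 4 blocked (median -0.03, adjusted p = 0.0769). T cell markers had 0 up and 0 down of 11, 0 and 0 adjusted over the list alone, 0 and 3 blocked (median -0.63, adjusted p = 0.0574). B cell markers had 0 up and 1 down of 11, 0 and 1 adjusted over the list alone, 0 and 3 blocked (median -0.52, adjusted p = 0.190). NK cell markers had 1 up and 0 down of 10, 1 and 1 adjusted over the list alone, 2 and 2 blocked (median -0.37, adjusted p = 0.726). Monocyte and macrophage markers had 1 up and 0 down of 14, 2 and 0 adjusted over the list alone, 3 and 2 blocked (median -0.49, adjusted p = 0.830). Endothelial and stromal markers had 0 up and 0 down of 13, 1 and 2 adjusted over the list alone, 1 and 2 blocked (median -0.57, adjusted p = 0.171). The median was below 0 while the test pointed up for interferon response, NK cell and monocyte lists. Within the erythroid list, the alpha globin gene Hba-a1 rose (3.65 ± 0.34, adjusted p = 0.000181).

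Of the 17 list calls against marrow after G-CSF, 6 held with an estimated correlation: immediate early, NF-kB, G-CSF and STAT3 response, myeloid priming, cholesterol synthesis and dendritic cell markers. The gene count was 285 without marrow array 3, 216 without marrow array 1, 186 without marrow array 2, 199 without G-CSF array 1, 743 without G-CSF array 2 (333 higher and 410 lower) and 190 without G-CSF array 3. Of the 52 genes named as changed here, 33 passed without any 1 array. Car1, Ccr9, Cd74, Cdkn1a, H2-Eb1, Hlf, Itgb1, Itgb7, Kif23, Klf1, Ly6a, Mllt3, Mmrn1, Ms4a3, Neil3, Nusap1, Pf4, Rhag and Xbp1 failed without at least 1. Klf1 had the highest adjusted p, 0.179, without G-CSF array 1. The HSC list lost its call without marrow array 1 or G-CSF array 2 (adjusted p = 0.262 to 0.289). The neutrophil list lost its call without marrow array 3, CWHM-823+tGro-b arrays 1 and 2, G-CSF array 2 or AMD3100 arrays 1 and 2 (adjusted p = 0.0514 to 0.376). The lymphoid priming list lost its call without G-CSF array 2 (adjusted p = 0.0598). The interferon response list gained a call without marrow arrays 1 and 2 or G-CSF array 2 (adjusted p = 0.0123 to 0.0289). The T cell list gained a call without marrow arrays 1 and 2 or CWHM-823+tGro-b array 3 (adjusted p = 0.0463 to 0.0496). The DNA replication list gained a call without marrow array 3 (adjusted p = 0.0136). The median log2 fold change of all genes was -0.25, and the share of increases moved with the scaling: 283 genes were higher and 70 lower with quantile normalization, 292 and 65 with normexp background correction, and 221 and 46 in the authors' table.

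LSK cells mobilized within 1 hour by AMD3100 were compared with the same marrow cells. Egr3 was 55.1-fold higher in blood (log2 fold change 5.78 ± 0.39, adjusted p = 0.000116, n = 3 per group), and the nuclear receptor gene Nr4a1 12.9-fold (3.69 ± 0.38, adjusted p = 0.00135). Klf2 rose by 3.95 ± 0.43, adjusted p = 0.00174, and Lmna, which encodes lamins A and C, by 3.01 ± 0.31, adjusted p = 0.00130. Lower in blood were Ccna2, the cyclin A2 gene of S and G2 phase (-2.64 ± 0.34, adjusted p = 0.00448), Gfi1, a transcription factor of stem cells (-2.31 ± 0.47, adjusted p = 0.0353), and Brca2, of DNA repair (-2.11 ± 0.32, adjusted p = 0.0107). The probe of Ccna2 maps to chromosome 3, 36463978 to 36464037 in mm9.

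A total of 338 genes passed after AMD3100, 122 higher and 216 lower. The count with the slide as a block was 3222, with 1389 higher and 1833 lower. Trib1, Atf3, Ahnak and Rasgef1b were the other largest increases (2.68 to 3.63, adjusted p = 0.000205 to 0.00477), and Hist1h2bg, Mettl18, Pbx3, Depdc1b and Armcx1 the other largest decreases (-2.21 to -2.05, adjusted p = 0.0107 to 0.0433). All of these moved the same way on all 3 slides. Gzmb was above background on 3 AMD3100 arrays and 0 marrow arrays, at least 8.90-fold higher (adjusted p = 0.000691); Drc7 and Tppp were at least 4.40-fold and 4.29-fold higher. Aspm, a mitotic spindle gene, Cpox, of heme synthesis, and Slamf1, which encodes the stem cell surface marker CD150, were at least 4.51-fold, 4.02-fold and 3.79-fold lower. None of the receptor genes passed: Cxcr4 was at -0.24 ± 0.27, adjusted p = 0.653, Cxcr2 at 0.35 ± 0.28, adjusted p = 0.528, Itga4 at -0.23 ± 0.31, adjusted p = 0.722 and Itgb1 at -0.02 ± 0.29, adjusted p = 0.977. Kit was at -0.22 ± 0.23, adjusted p = 0.627, Ly6a at 0.04 ± 0.33, adjusted p = 0.954 and the Csf3r probe at 0.11 ± 0.24, adjusted p = 0.836.

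Genes of mitosis fell after AMD3100 (median -1.24, adjusted p = 3.43e-15). In this list 0 of 28 measured members rose, 9 fell and 19 did not pass (0 rose and 20 fell adjusted over the list alone, 0 and 19 blocked), with Birc5 (-1.80 ± 0.31), Prc1 (-1.68 ± 0.26) and Ube2c (-1.81 ± 0.32) lower beside Ccna2. Lymphoid priming genes rose (median 0.75, adjusted p = 2.70e-05). Here 2 of 22 measured members rose, 0 fell and 20 did not pass (8 rose and 0 fell adjusted over the list alone, 9 and 0 blocked), among them Tcf7, a T-lineage transcription factor (2.31 ± 0.44). NF-kB target and inflammatory genes also rose (median 0.48, adjusted p = 0.00189). Here 2 of 25 measured members rose, 0 fell and 23 did not pass (4 rose and 0 fell adjusted over the list alone, 5 and 0 blocked), Tnfaip3 (2.07 ± 0.39) and Tnf (1.73 ± 0.35). Immediate early genes stood higher (median 1.19, adjusted p = 2.91e-16, adjusted p = 0.0792 with an estimated correlation). Here 12 of 30 measured members rose, 0 fell and 18 did not pass (19 rose and 0 fell adjusted over the list alone); Klf6 rose by 2.29 ± 0.27. HSC genes stood lower (median -0.80, adjusted p = 3.88e-08, adjusted p = 0.124 with an estimated correlation; 0 up and 6 down of 29, 1 and 14 adjusted over the list alone, 1 and 16 blocked), among them Hlf (-1.31 ± 0.23) and Mecom (-1.32 ± 0.26), both transcription factors of stem cells. DNA replication genes were lower as a list (median -0.65, adjusted p = 9.13e-06, adjusted p = 0.312 with an estimated correlation; 0 up and 0 down of 29, 0 and 6 adjusted over the list alone, 1 and 8 blocked). So were oxidative phosphorylation genes (median -0.24, adjusted p = 0.00260, adjusted p = 0.632 with an estimated correlation; 0 up and 1 down of 30, 0 and 2 adjusted over the list alone, 0 and 4 blocked), with Sdha of respiratory complex II at -1.37 ± 0.29. T cell markers were higher (median 0.55, adjusted p = 0.0273, adjusted p = 0.275 with an estimated correlation; 1 up and 0 down of 11, 2 and 0 adjusted over the list alone, 2 and 0 blocked). NK cell markers were higher (median 0.48, adjusted p = 0.0241, adjusted p = 0.275 with an estimated correlation; 1 up and 0 down of 10, 2 and 0 adjusted over the list alone, 4 and 0 blocked). Mast cell and basophil markers were higher (median 0.67, adjusted p = 0.00410, adjusted p = 0.0681 with an estimated correlation; 3 up and 0 down of 10, 3 and 0 adjusted over the list alone, 3 and 1 blocked). Tcf7 was the risen T cell member, Gzmb the risen NK cell member, and Gzmb, Hdc (2.51 ± 0.42) and Cpa3 (1.71 ± 0.29) the risen mast cell members. The heat shock and stress list passed only with the slide as a block (median -0.28, adjusted p = 0.0642, 0.0429 blocked). The other 15 lists passed in neither fit, and the calls for lymphoid priming, mitosis and NF-kB held with an estimated correlation.

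After AMD3100 the gene count was 70 without marrow array 1 (41 higher and 29 lower), 66 without marrow array 2 (41 higher and 25 lower), 205 without marrow array 3, 101 without AMD3100 array 1 and 169 without AMD3100 array 2. Without marrow array 3, which carries neutrophil transcripts, 76 genes were higher and 129 lower, and the immediate early list kept an adjusted p of 3.20e-12 with the preset correlation. Of the 34 genes named as changed here, 12 passed without any 1 array. Armcx1, Aspm, Birc5, Brca2, Cpa3, Depdc1b, Drc7, Gfi1, Hdc, Hist1h2bg, Hlf, Mecom, Mettl18, Pbx3, Prc1, Sdha, Slamf1, Tcf7, Tnf, Tnfaip3, Tppp and Ube2c failed without at least 1. Sdha had the highest adjusted p, 0.177, without marrow array 1. The oxidative phosphorylation list lost its call without marrow array 3 or AMD3100 array 2 (adjusted p = 0.0960 to 0.127). The NK cell list lost its call without AMD3100 arrays 2 and 3 (adjusted p = 0.0538 to 0.0543). The T cell list lost its call without AMD3100 arrays 2 and 3 (adjusted p = 0.0538 to 0.0838). The heat shock and stress list gained a call without marrow arrays 2 and 3 or AMD3100 array 1 (adjusted p = 0.0350 to 0.0427). The median log2 fold change of all genes was 0.11, and the count moved with the scaling: 256 genes were higher and 487 lower with quantile normalization, 74 and 96 with normexp background correction, and 196 and 351 in the authors' table.

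The third mobilization joined CWHM-823 with tGro-b. Against marrow, Egr3 was 87.0-fold higher in these blood LSK cells (log2 fold change 6.44 ± 0.39, adjusted p = 8.92e-06, n = 3 per group). Atf3, a stress-induced transcription factor, rose by 4.94 ± 0.41, adjusted p = 8.50e-05, and Nr4a1 by 4.84 ± 0.38, adjusted p = 7.80e-05. The alpha globin genes Hba-a1 (4.46 ± 0.34, adjusted p = 7.34e-05) and Hba-a2 (4.89 ± 0.38, adjusted p = 7.51e-05) were also among the largest increases. Nr4a3, a further nuclear receptor gene of the immediate early list, was at least 20.8-fold higher (adjusted p = 7.57e-07), since 0 marrow arrays had it above background.

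Of the 88 genes that passed after CWHM-823+tGro-b, 81 were higher and 7 lower. With the slide as a block 257 passed, 183 higher and 74 lower, 87 of the 88 among them. Trib1, Klf2 and Rasgef1b completed the largest increases (up to 4.63, adjusted p = 1.36e-05 to 0.000283). Spag5, a gene of the mitotic spindle (-2.09 ± 0.37, adjusted p = 0.0329), and Gucy1b2 (-1.32 ± 0.24, adjusted p = 0.0462) were the only decreases that met the rule for named genes, and all of these moved the same way on all 3 slides. The beta globin gene Hbb-bt was at least 12.8-fold and Csrnp1 at least 12.6-fold higher, both with 0 marrow arrays above background. N4bp3 was at least 2.48-fold lower. The Hba-a1 probe (chromosome 11, 32183955 to 32184014 in mm9) read 3.85, 3.66 and 3.12 log2 units over the 75th percentile in this group and -1.28, -1.39 and -0.05 in marrow. No receptor gene passed: Itgb1 was at 0.87 ± 0.29, adjusted p = 0.489, Itga4 at 0.09 ± 0.31, adjusted p = 1.00, Cxcr2 at -0.14 ± 0.28, adjusted p = 1.00 and Cxcr4 at -0.43 ± 0.27, adjusted p = 1.00. Kit was at -0.05 ± 0.23, adjusted p = 1.00, Ly6a at 0.24 ± 0.33, adjusted p = 1.00 and the Csf3r probe at -0.28 ± 0.24, adjusted p = 1.00.

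Immediate early genes rose (median 2.06, adjusted p = 3.63e-67). Here 15 of 30 measured members rose, 0 fell and 15 did not pass (24 rose and 0 fell adjusted over the list alone); Nr4a2 rose by 3.56 ± 0.30. NF-kB target and inflammatory genes rose (median 0.35, adjusted p = 2.24e-12). Here 3 of 25 measured members rose, 0 fell and 22 did not pass (7 rose and 0 fell adjusted over the list alone, 5 and 0 blocked), among them Tnfaip3 (3.03 ± 0.39) and the chemokine gene Ccl4 (2.91 ± 0.52). Lymphoid priming genes rose (median 0.49, adjusted p = 3.45e-09). Here 1 of 22 measured members rose, 0 fell and 21 did not pass (7 rose and 0 fell adjusted over the list alone, 2 and 0 blocked). That member was Vpreb1, part of the surrogate light chain of B-cell precursors (2.18 ± 0.35). Mast cell and basophil markers rose (median 0.80, adjusted p = 7.40e-06; 2 up and 0 down of 10, 3 and 0 adjusted over the list alone), with Hdc at 3.96 ± 0.42 and Gzmb at least 6.37-fold higher. Mitosis genes fell as a list (median -0.97, adjusted p = 1.81e-22), although 0 of 28 measured members rose, 0 fell and 28 did not pass (0 rose and 18 fell adjusted over the list alone, 0 and 5 blocked). These 5 list calls held with an estimated correlation, and the following 11 did not.

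Another 7 lists were higher. Cholesterol synthesis had 0 up and 0 down of 23, 1 and 0 adjusted over the list alone, 3 and 0 blocked. Oxidative phosphorylation had 0 up and 0 down of 30, 0 and 0 adjusted over the list alone. Heat shock and stress had 0 up and 0 down of 21, 2 and 0 adjusted over the list alone, 2 and 0 blocked. Ribosome biogenesis and MYC had 0 up and 0 down of 25, 0 and 0 adjusted over the list alone. Hypoxia and glycolysis had 1 up and 0 down of 26, 1 and 0 adjusted over the list alone. Slc2a3, a glucose transporter gene, was the risen glycolysis member (2.13 ± 0.29). The G-CSF and STAT3 response (2 up and 0 down of 21, 6 and 2 adjusted over the list alone, 4 and 0 blocked) was led by Socs3 (3.06 ± 0.32) and Junb (2.15 ± 0.40). The quiescence list (2 up and 0 down of 20, 7 and 1 adjusted over the list alone, 5 and 1 blocked) was led by Nr4a1 and Klf4 (3.48 ± 0.34). These 7 lists had medians of 0.15 to 0.56, with adjusted p = 2.51e-08 to 0.00439, and adjusted p = 0.0837 to 0.363 with an estimated correlation. The erythroid list pointed up by its test and its mean of 0.53 but not by its median (median -0.09, adjusted p = 0.0438, 0.177 blocked, adjusted p = 0.332 with an estimated correlation; 2 up and 0 down of 21, 4 and 1 adjusted over the list alone), with Hba-a1 and Hbb-bt the risen members. Lower were HSC genes (median -0.25, adjusted p = 0.00116, adjusted p = 0.309 with an estimated correlation; 0 up and 0 down of 29, 0 and 0 adjusted over the list alone, 1 and 0 blocked). DNA replication genes were lower (median -0.20, adjusted p = 0.0459, 0.0742 blocked, adjusted p = 0.491 with an estimated correlation; 0 up and 0 down of 29, 0 and 0 adjusted over the list alone). Neutrophil markers were lower as well (median -1.13, adjusted p = 0.000435, adjusted p = 0.251 with an estimated correlation; 0 up and 0 down of 10, 0 and 0 adjusted over the list alone). The other 10 lists did not pass. Leaving out marrow array 3 left 65 genes, and the count was 53 without CWHM-823+tGro-b array 1. Of the 24 genes named as changed here, 18 passed without any 1 array. Ccl4, Gucy1b2, Junb, N4bp3, Spag5 and Vpreb1 failed without at least 1. Junb had the highest adjusted p, 0.234, without CWHM-823+tGro-b array 1. The HSC list lost its call without marrow array 1 or CWHM-823+tGro-b array 2 (adjusted p = 0.0952 to 0.250). The erythroid list lost its call without marrow array 2, CWHM-823+tGro-b array 1 or G-CSF arrays 1, 2 and 3 (adjusted p = 0.0510 to 0.821). The hypoxia and glycolysis list lost its call without marrow array 2 or CWHM-823+tGro-b array 1 (adjusted p = 0.102 to 0.419). The ribosome biogenesis and MYC list lost its call without marrow array 2 or CWHM-823+tGro-b array 1 (adjusted p = 0.131 to 0.154). The DNA replication list lost its call without marrow array 3, CWHM-823+tGro-b arrays 2 and 3, G-CSF arrays 1, 2 and 3 or AMD3100 arrays 1 and 3 (adjusted p = 0.0509 to 0.888). The neutrophil list lost its call without marrow array 3 (adjusted p = 0.146).

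**Figure D1:**
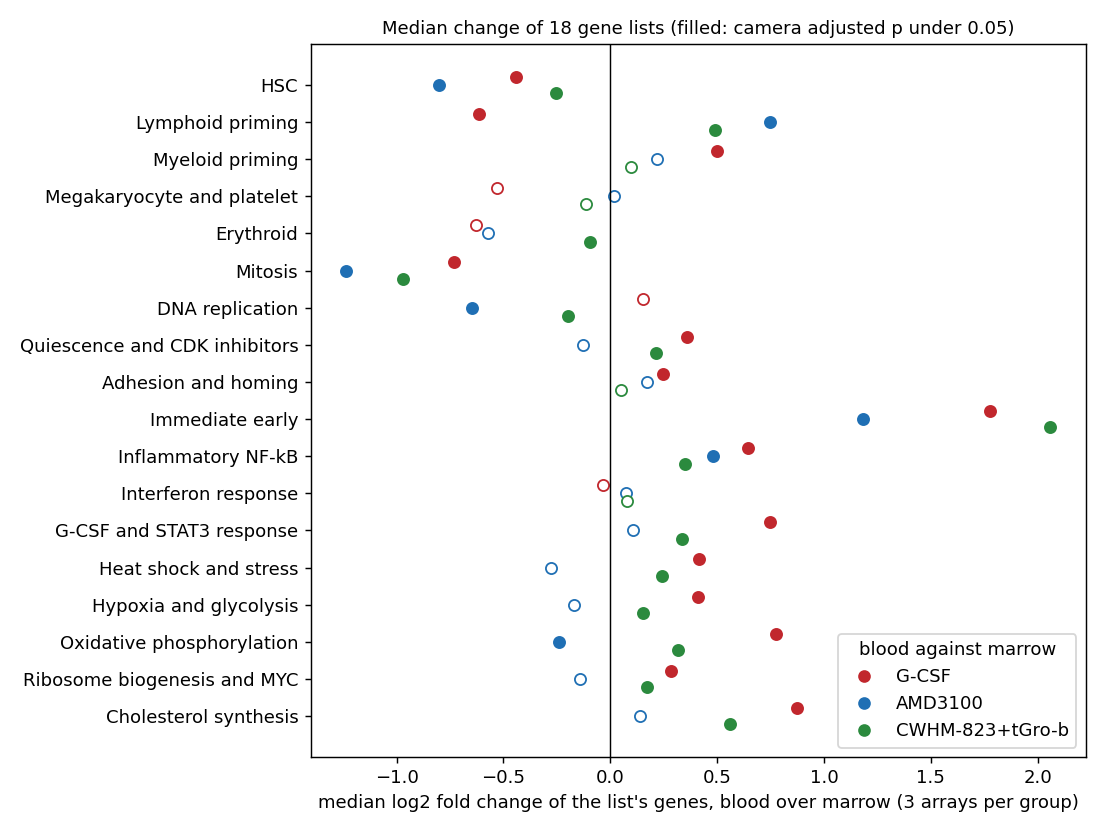
Median log2 fold change against marrow (x axis, log2 units) of the measured members of each of the 18 gene lists (y axis) for the 3 blood groups, each with 3 arrays; filled circles mark lists with a camera adjusted p under 0.05. Immediate early genes stood highest after G-CSF (1.78), AMD3100 (1.19) and CWHM-823+tGro-b (2.06), and lymphoid priming genes were at -0.62, 0.75 and 0.49.

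The average of the 3 blood groups was also tested against marrow, 9 arrays against 3. A gene can pass there through only some of the treatments. Only 1 gene was lower in all 3 single comparisons, and it is none of the decreases named here. Egr3 (5.57 ± 0.32, adjusted p = 5.90e-06), Klf2 (4.46 ± 0.35, adjusted p = 4.86e-05), Trib1 (4.33 ± 0.24, adjusted p = 5.90e-06), Nr4a1 (4.03 ± 0.31, adjusted p = 4.85e-05) and Atf3 (3.90 ± 0.33, adjusted p = 9.38e-05) rose most among genes above background on all 12 arrays. Ccna2 fell most (-1.74 ± 0.28, adjusted p = 0.0120), followed by Mtss2, Hoxa3, Slit2 and Fbxo5, an inhibitor of the anaphase-promoting complex (-1.47 to -1.36, adjusted p = 0.0116 to 0.0401). A total of 183 genes passed, 133 higher and 50 lower, or 669 with the slide as a block (317 higher and 352 lower). Leaving out 1 array gave 108 without marrow array 1 and 90 without marrow array 2, and the count without marrow array 3 was 132. The receptor genes did not pass, with Itgb1 at 0.76 ± 0.24, adjusted p = 0.245, Ly6a at 0.65 ± 0.27, adjusted p = 0.507, Cxcr4 at -0.40 ± 0.22, adjusted p = 0.698, Cxcr2 at 0.22 ± 0.23, adjusted p = 0.956 and Itga4 at -0.07 ± 0.26, adjusted p = 0.996. Kit was at -0.15 ± 0.19, adjusted p = 0.979 and the Csf3r probe at -0.27 ± 0.20, adjusted p = 0.849. Of the 10 genes named as changed here, 5 passed without any 1 array. Ccna2, Fbxo5, Hoxa3, Mtss2 and Slit2 failed without at least 1. Hoxa3 had the highest adjusted p, 0.230, without marrow array 1.

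Calls overlapped between treatments. 48 genes were higher than marrow in each of the 3 comparisons, among them Egr2, Nr4a3, Spry1, Cd69 and Sgk1, and 1 was lower in each. G-CSF and AMD3100 had 66 increases and 16 decreases in common, against 1.44 and 1.20 for independent calls, and 4 genes changed in opposite directions. G-CSF and CWHM-823+tGro-b had 62 increases and 2 decreases in common (0.957 and 0.0388 for independent calls), and AMD3100 and CWHM-823+tGro-b 54 and 4 (0.415 and 0.0635). Those expectations leave out the shared marrow arrays, which push calls the same way. Across genes, which are not independent replicates, the log2 fold changes against marrow had a Pearson r of -0.0635 for G-CSF and AMD3100, 0.578 for G-CSF and CWHM-823+tGro-b, and 0.353 for AMD3100 and CWHM-823+tGro-b. Within single slides r was 0.0102, 0.181 and 0.139 for the first pair. It was 0.610, 0.513 and 0.479 for the second and 0.281, 0.454 and 0.391 for the third. Simulated groups with no change gave 0.50, 0.501 and 0.501, because of the common marrow arrays, above every slide of the first pair. The covariances were -0.0281, 0.185 and 0.108, against 0.0855, 0.0858 and 0.0858 in the simulated groups.

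**Figure D2:**
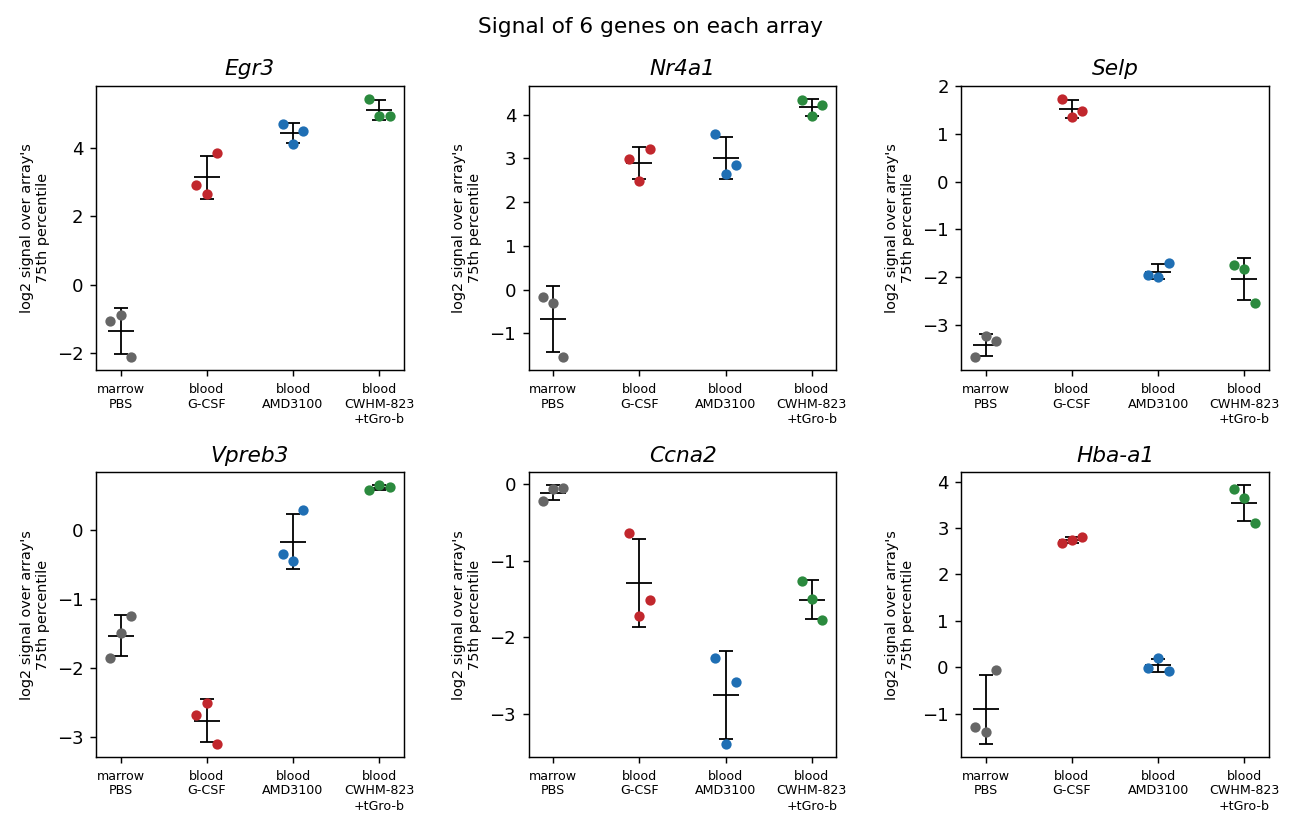
Normalized log2 intensity over the array's 75th percentile (y axis) of 6 genes on each of the 12 arrays, by group (x axis). Points are arrays, and the bar and whiskers give the mean and SD of 3 arrays. Egr3 and Nr4a1 were higher on the blood arrays than on the marrow arrays, and Hba-a1 was highest after CWHM-823+tGro-b.

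The blood groups were also set against each other, which holds the tissue constant while the treatment times differ. With G-CSF (5 days) against AMD3100 (1 hour), Selp was 10.7-fold higher (log2 fold change 3.42 ± 0.26, adjusted p = 0.000212, n = 3 per group), and Bhlhe40, a transcription repressor, 12.3-fold (3.62 ± 0.50, adjusted p = 0.00386). Sbno2 (3.21 ± 0.37), Tgfbi (3.18 ± 0.32) and Pmaip1, which encodes the pro-apoptotic protein Noxa (3.18 ± 0.26), were the next largest increases (adjusted p = 0.000212 to 0.00129). Lower after G-CSF were Tcf7 (-3.05 ± 0.44, adjusted p = 0.00417), Cd74 (-2.76 ± 0.44, adjusted p = 0.00504), and Ccdc177, Scin and Dlx6 (-3.08 to -2.74, adjusted p = 0.00221 to 0.00847). The progenitor gene Ms4a3 was at least 17.3-fold higher, Aqp1 at least 7.96-fold and Thbs3 at least 5.08-fold, with 0 AMD3100 arrays above background. Il7r, the interleukin-7 receptor gene of lymphoid cells, was at least 6.46-fold lower, the B-cell gene Bank1 at least 5.42-fold and Cyp2d37-ps at least 4.97-fold.

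In this comparison 7390 genes passed, 3008 higher and 4382 lower after G-CSF, and 14904 with the slide as a block (5485 and 9419). Ly6a (1.61 ± 0.33, adjusted p = 0.0105) and Itgb1 (1.44 ± 0.29, adjusted p = 0.00966) were higher after G-CSF. The Csf3r probe, placed on another chromosome, read lower (-0.74 ± 0.24, adjusted p = 0.0386), but not without marrow array 2, G-CSF arrays 1 and 3 or AMD3100 arrays 1, 2 and 3 (adjusted p = 0.0530 to 0.139). Cxcr4 (-0.30 ± 0.27, adjusted p = 0.367), Cxcr2 (0.10 ± 0.28, adjusted p = 0.784), Itga4 (0.17 ± 0.31, adjusted p = 0.665) and Kit (0.06 ± 0.23, adjusted p = 0.852) did not pass. Genes named as changed moved the same way on all 3 slides. The median log2 fold change of all genes was -0.37, and the split moved with the scaling: 3316 genes were higher and 2605 lower with quantile normalization, and 3068 and 2547 in the authors' table. Leaving out 1 array gave counts of 1470 without G-CSF array 1, 2228 without G-CSF array 3 (1188 higher and 1040 lower), 2920 without AMD3100 array 1 and 2515 without AMD3100 array 2.

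Lymphoid priming genes were lower after G-CSF than after AMD3100 (median -1.24, adjusted p = 0.000137, adjusted p = 0.121 with an estimated correlation). In the list 1 of 22 measured members rose, 13 fell and 8 did not pass (1 rose and 13 fell adjusted over the list alone); Ccr9 (-2.55 ± 0.29), Blnk, an adaptor of B-cell receptor signalling (-3.30 ± 0.49), and Dntt, the terminal transferase (-1.53 ± 0.26), were among the lower members. T cell markers were lower (median -1.03, adjusted p = 0.00925, adjusted p = 0.216 with an estimated correlation; 0 up and 5 down of 11, 0 and 5 adjusted over the list alone), with Cd5 at -2.17 ± 0.36. Dendritic cell markers were lower (median -1.17, adjusted p = 0.00221, adjusted p = 0.121 with an estimated correlation; 0 up and 7 down of 11, 0 and 8 adjusted over the list alone), with H2-Eb1 at -4.37 ± 0.66. Oxidative phosphorylation genes were higher (median 0.95, adjusted p = 2.96e-12, adjusted p = 0.216 with an estimated correlation). Here 20 of 30 measured members rose, 0 fell and 10 did not pass (22 rose and 0 fell adjusted over the list alone). Ndufv1 of complex I (1.98 ± 0.30), Sdha of complex II (1.78 ± 0.29) and Uqcrfs1 of complex III (1.32 ± 0.25) were among them. The G-CSF and STAT3 response was higher (median 1.40, adjusted p = 1.46e-05, adjusted p = 0.155 with an estimated correlation). It had 12 up and 1 down of 21, and 12 and 1 adjusted over the list alone. Bcl3 (3.15 ± 0.23), Pim2 (2.15 ± 0.27) and Cebpb (1.58 ± 0.28) were among the higher members. The lower member was the Csf3r probe, placed on another chromosome. Myeloid priming genes (median 0.12, adjusted p = 0.0247, 0.0611 blocked, adjusted p = 0.227 with an estimated correlation; 6 up and 1 down of 19, 6 and 1 adjusted over the list alone, 6 and 2 blocked) included Prtn3 (1.70 ± 0.27) and Elane (2.41 ± 0.73), while Irf8, a transcription factor of monocytes and dendritic cells, was lower (-1.14 ± 0.28). HSC genes were higher (median 0.11, adjusted p = 0.0453, 0.0636 blocked, adjusted p = 0.494 with an estimated correlation; 7 up and 0 down of 29, 4 and 0 adjusted over the list alone, 7 and 2 blocked), among them Procr, the endothelial protein C receptor gene (1.09 ± 0.36), and Hoxb4 (1.60 ± 0.47).

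A further 8 lists were higher after G-CSF than after AMD3100. Mitosis had 11 up and 2 down of 28, 12 and 2 adjusted over the list alone, with Birc5 at 1.38 ± 0.31. DNA replication had 10 up and 2 down of 29, 12 and 2 adjusted over the list alone, 17 and 3 blocked, with Fen1 at 1.53 ± 0.37. Quiescence and CDK inhibitor genes had 4 up and 0 down of 20, 3 and 0 adjusted over the list alone, with Cdkn2d at 2.28 ± 0.33. Cholesterol synthesis had 8 up and 0 down of 23, 9 and 0 adjusted over the list alone, 15 and 0 blocked. Hypoxia and glycolysis had 9 up and 0 down of 26, 10 and 0 adjusted over the list alone, 15 and 1 blocked, with the phosphofructokinase gene Pfkl at 1.74 ± 0.32. Heat shock and stress had 10 up and 1 down of 21, 13 and 1 adjusted over the list alone, 13 and 2 blocked, with Bag3 at 1.81 ± 0.28. Ribosome biogenesis and MYC had 5 up and 0 down of 25, 4 and 0 adjusted over the list alone, 14 and 3 blocked. Adhesion and homing genes had 9 up and 3 down of 32, 10 and 3 adjusted over the list alone, 14 and 7 blocked, with Esam at 1.53 ± 0.26. Their medians ran from 0.35 to 0.82 with adjusted p = 6.25e-05 to 0.0148, and adjusted p = 0.176 to 0.366 with an estimated correlation. No list call between these groups held with an estimated correlation, and with the preset one the call was lost for HSC (0.0653 to 0.0749 without G-CSF arrays 1 and 3 or AMD3100 array 2). Of the 40 genes named as changed here, 33 passed without any 1 array. Bank1, Birc5, Elane, Fen1, Hoxb4, Irf8 and Procr failed without at least 1. Procr had the highest adjusted p, 0.143, without AMD3100 array 2.

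G-CSF was then set against CWHM-823+tGro-b. Vpreb3 (-3.37 ± 0.27, adjusted p = 0.000114), Igll1 (-3.19 ± 0.45, adjusted p = 0.00639) and Vpreb1 (-3.00 ± 0.35, adjusted p = 0.00192), which make the surrogate light chain or accompany its assembly in B-cell precursors, were lower after G-CSF (n = 3 per group). Pou2af1, a B-cell coactivator (-3.09 ± 0.39, adjusted p = 0.00314), and Spry1, an inhibitor of growth factor signalling (-2.58 ± 0.22, adjusted p = 0.000154), were lower as well. Pirb, an inhibitory receptor of myeloid cells, was 12.1-fold higher after G-CSF (3.60 ± 0.29, adjusted p = 0.000114). Tgfbi, Col18a1, Selp and Dlk1 were the other largest increases (3.37 to 3.59, adjusted p = 8.49e-05 to 0.000203).

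Jchain, the joining chain of secreted immunoglobulins, was at least 11.3-fold lower, Il7r at least 5.22-fold and Ddx4 at least 4.79-fold, with 0 G-CSF arrays above background. Cd200r4 was at least 10.1-fold, Pira7 at least 6.52-fold and the kinase gene Map3k8 at least 5.19-fold higher. 149 genes passed, 88 higher and 61 lower after G-CSF, against 523 with the slide as a block (266 and 257). Leaving out 1 array gave counts of 78 without CWHM-823+tGro-b array 2, 112 without CWHM-823+tGro-b array 3 (53 higher and 59 lower), 73 without G-CSF array 1, 184 without G-CSF array 2 (80 higher and 104 lower) and 71 without G-CSF array 3, and the authors' values gave 62 higher and 37 lower. The median log2 fold change of all genes was -0.14. None of the receptor genes passed: Ly6a was at 1.41 ± 0.33, adjusted p = 0.118, 0.0314 blocked, Itgb1 at 0.55 ± 0.29, adjusted p = 0.542, Itga4 at -0.14 ± 0.31, adjusted p = 0.857 and Cxcr2 at 0.59 ± 0.28, adjusted p = 0.512. Cxcr4 was at -0.11 ± 0.27, adjusted p = 0.870, Kit at -0.12 ± 0.23, adjusted p = 0.839 and the Csf3r probe at -0.35 ± 0.24, adjusted p = 0.606.

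Lymphoid priming genes were lower after G-CSF than after CWHM-823+tGro-b (median -0.96, adjusted p = 2.58e-10). Here 0 of 22 measured members rose, 5 fell and 17 did not pass (1 rose and 12 fell adjusted over the list alone, 1 and 10 blocked); Ccr9 (-2.16 ± 0.29) and Blnk (-3.48 ± 0.49) were among them. Dendritic cell markers were lower (median -0.56, adjusted p = 2.67e-05; 0 up and 2 down of 11, 0 and 5 adjusted over the list alone), with H2-Eb1 at -4.34 ± 0.66 and Cd74 at -2.46 ± 0.44. Myeloid priming genes were higher (median 0.33, adjusted p = 1.62e-05; 3 up and 0 down of 19, 4 and 1 adjusted over the list alone), with Ctsg at 1.81 ± 0.31 and Prtn3 at 1.66 ± 0.27. These were the calls that held with an estimated correlation. Immediate early genes were lower after G-CSF (median -0.43, adjusted p = 8.39e-05, adjusted p = 0.310 with an estimated correlation; 0 up and 4 down of 30, 1 and 9 adjusted over the list alone, 1 and 6 blocked), with Nr4a3 at -4.51 ± 0.30, Nr4a2 at -2.36 ± 0.30 and Dusp6 at -1.62 ± 0.27. Erythroid genes were lower (median -0.80, adjusted p = 8.55e-05, adjusted p = 0.108 with an estimated correlation; 0 up and 0 down of 21, 0 and 3 adjusted over the list alone, 0 and 3 blocked). T cell markers were lower (median -0.55, adjusted p = 0.000848, adjusted p = 0.0821 with an estimated correlation; 0 up and 0 down of 11, 0 and 2 adjusted over the list alone, 0 and 2 blocked). B cell markers were lower (median -0.44, adjusted p = 0.00408, adjusted p = 0.0599 with an estimated correlation; 0 up and 2 down of 11, 0 and 3 adjusted over the list alone). The B-cell genes Cd79a (-2.28 ± 0.38) and Pax5 (-1.69 ± 0.31) were the lower B cell members. The G-CSF and STAT3 response was higher (median 0.40, adjusted p = 1.95e-07, adjusted p = 0.0599 with an estimated correlation; 4 up and 0 down of 21, 6 and 2 adjusted over the list alone), with Bcl3 at 2.92 ± 0.23 and Il4ra at 1.48 ± 0.25.

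Another 7 lists stood higher after G-CSF than after CWHM-823+tGro-b without a single member that passed over all genes. Oxidative phosphorylation had 0 up and 0 down of 30, 0 and 0 adjusted over the list alone. Adhesion and homing had 0 up and 0 down of 32, 3 and 0 adjusted over the list alone, 5 and 0 blocked. Cholesterol synthesis had 0 up and 0 down of 23, 0 and 0 adjusted over the list alone, 1 and 0 blocked. DNA replication had 0 up and 0 down of 29, 0 and 0 adjusted over the list alone. Hypoxia and glycolysis had 0 up and 0 down of 26, 0 and 0 adjusted over the list alone, 1 and 1 blocked. Mitosis had 0 up and 0 down of 28, 0 and 0 adjusted over the list alone, 1 and 0 blocked. Heat shock and stress had 0 up and 0 down of 21, 0 and 0 adjusted over the list alone, 1 and 0 blocked. Their medians were 0.19 to 0.37, with adjusted p = 3.27e-08 to 0.010, and adjusted p = 0.0783 to 0.457 with an estimated correlation. Of the 29 genes named as changed here, 18 passed without any 1 array. Cd74, Cd79a, Ctsg, Dusp6, H2-Eb1, Il4ra, Il7r, Jchain, Map3k8, Pax5 and Prtn3 failed without at least 1. Pax5 had the highest adjusted p, 0.136, without CWHM-823+tGro-b array 2. The heat shock and stress list lost its call without CWHM-823+tGro-b array 2 (adjusted p = 0.12). The hypoxia and glycolysis list lost its call without CWHM-823+tGro-b array 2 or G-CSF array 1 (adjusted p = 0.12 to 0.170). The mitosis list lost its call without G-CSF array 1 (adjusted p = 0.0798). The immediate early list lost its call without G-CSF array 2 (adjusted p = 0.133).

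The last pair set CWHM-823+tGro-b against AMD3100. Globin genes were higher after CWHM-823+tGro-b: Hba-a1 by 11.4-fold (log2 fold change 3.51 ± 0.34, adjusted p = 0.00336, n = 3 per group), Hba-a2 by 11.2-fold (3.49 ± 0.38, adjusted p = 0.00336) and Hbb-bt by at least 9.27-fold (adjusted p = 0.00336). The immediate early genes Nr4a3 (2.55 ± 0.30, adjusted p = 0.00463) and Csrnp1 (2.12 ± 0.27, adjusted p = 0.00958) and the signalling inhibitor Spry1 (2.09 ± 0.22, adjusted p = 0.00336) were also higher. Cpox, of heme synthesis, was at least 3.22-fold and Aqp1, a water channel of red cells, at least 2.17-fold higher. Olfr93 (-1.81 ± 0.21, adjusted p = 0.00412) and Dpysl3 (-1.46 ± 0.24, adjusted p = 0.0425) were lower, and Ccer1, Lgi2 and N4bp3 were at least 2.95-fold, 2.85-fold and 2.60-fold lower. 35 genes passed, 28 higher and 7 lower, against 4010 with the slide as a block (2005 and 2005). Leaving out 1 array gave counts of 11 without CWHM-823+tGro-b array 1, 58 without CWHM-823+tGro-b array 2 (25 higher and 33 lower), 54 without G-CSF array 2, 13 without AMD3100 array 1 and 72 without AMD3100 array 3. With normexp background correction 9 genes were higher and 0 lower, with quantile normalization 86 and 22, and with the authors' values 6 and 2. The median log2 fold change of all genes was -0.16. Itgb1 was at 0.89 ± 0.29, adjusted p = 0.164, 0.0422 blocked, Itga4 at 0.31 ± 0.31, adjusted p = 0.547, Cxcr4 at -0.19 ± 0.27, adjusted p = 0.663 and Cxcr2 at -0.49 ± 0.28, adjusted p = 0.332. Kit was at 0.17 ± 0.23, adjusted p = 0.644, Ly6a at 0.20 ± 0.33, adjusted p = 0.717 and the Csf3r probe at -0.39 ± 0.24, adjusted p = 0.356.

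Immediate early genes were higher after CWHM-823+tGro-b than after AMD3100 (median 0.66, adjusted p = 4.14e-10, adjusted p = 0.317 with an estimated correlation). Here 2 of 30 measured members rose, 0 fell and 28 did not pass (9 rose and 0 fell adjusted over the list alone, 10 and 0 blocked). Oxidative phosphorylation was higher (median 0.61, adjusted p = 2.65e-10, adjusted p = 0.317 with an estimated correlation; 0 up and 0 down of 30, 9 and 0 adjusted over the list alone, 11 and 0 blocked). Erythroid genes were higher (median 0.90, adjusted p = 0.000376, adjusted p = 0.317 with an estimated correlation; 2 up and 0 down of 21, 9 and 0 adjusted over the list alone, 9 and 1 blocked). HSC genes were higher (median 0.53, adjusted p = 0.000324, adjusted p = 0.320 with an estimated correlation; 0 up and 0 down of 29, 8 and 0 adjusted over the list alone, 9 and 0 blocked). In the remaining 8 lists that passed, 0 members passed over all genes. Mitosis had 0 up and 0 down of 28, 0 and 0 adjusted over the list alone, 1 and 1 blocked. DNA replication had 0 up and 0 down of 29, 0 and 0 adjusted over the list alone, 3 and 1 blocked. Quiescence and CDK inhibitors had 0 up and 0 down of 20, 0 and 0 adjusted over the list alone, 5 and 0 blocked. The G-CSF and STAT3 response had 0 up and 0 down of 21, 2 and 0 adjusted over the list alone, 4 and 0 blocked. Heat shock and stress had 0 up and 0 down of 21, 6 and 0 adjusted over the list alone, 9 and 0 blocked. Hypoxia and glycolysis had 0 up and 0 down of 26, 0 and 0 adjusted over the list alone, 6 and 0 blocked. Ribosome biogenesis and MYC had 0 up and 0 down of 25, 0 and 0 adjusted over the list alone, 5 and 1 blocked. Cholesterol synthesis had 0 up and 0 down of 23, 0 and 0 adjusted over the list alone, 5 and 0 blocked. These 8 had medians of 0.27 to 0.61, with adjusted p = 3.73e-05 to 0.0448, and adjusted p = 0.317 to 0.348 with an estimated correlation. The NK cell markers passed only with the slide as a block (median -0.43, adjusted p = 0.0640, 0.04997 blocked) or without AMD3100 array 1 (adjusted p = 0.0348), and the call was lost for mitosis (0.0528 to 0.199 without marrow array 3, CWHM-823+tGro-b arrays 1 and 2 or AMD3100 array 3). Of the 13 genes named as changed here, 7 passed without any 1 array. Aqp1, Cpox, Csrnp1, Dpysl3, Lgi2 and N4bp3 failed without at least 1. Dpysl3 had the highest adjusted p, 0.190, without CWHM-823+tGro-b array 1. Over the 3 blood groups together, 2832 genes differed by the moderated F-test, and 12714 with the slide as a block. That count was 1474 without marrow array 2, 258 without G-CSF array 1, 5392 without G-CSF array 2, 397 without G-CSF array 3, 416 without AMD3100 array 1 and 459 without AMD3100 array 2.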

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

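Of the tests below, those of signal distributions, array brightness, neutrophil genes, handling, erythroid progenitors and splits within slides were chosen after the results were seen, as was the condition on single slides for the neutrophil genes. The test of probe GC content was added once the gene counts were known, with its bound set before its own result.

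The results in this paragraph are opposite changes against the shared marrow arrays, with the difference between the treatments tested directly. Vpreb3 fell with G-CSF (-1.23 ± 0.27, adjusted p = 0.0446) and rose with AMD3100 (1.36 ± 0.27, adjusted p = 0.0336) and with CWHM-823+tGro-b (2.14 ± 0.27, adjusted p = 0.00266). Its differences were -2.59 ± 0.27 for G-CSF against AMD3100 (adjusted p = 0.000761) and -3.37 ± 0.27 against CWHM-823+tGro-b (adjusted p = 0.000114). Tnfsf10, which encodes the death ligand TRAIL, rose with G-CSF (1.097 ± 0.23, adjusted p = 0.0349) and fell with AMD3100 (-1.05 ± 0.23, adjusted p = 0.0477), a difference of 2.15 ± 0.23 (adjusted p = 0.000788). These 2 genes moved the same way on all 3 slides in each of these comparisons. Their differences between treatments passed without any 1 array, while each change against marrow after G-CSF or AMD3100 failed without at least 1 array, with a highest adjusted p of 0.198 for Tnfsf10 without marrow array 1. Amacr and Gfra2 met the same condition, but with 2 and 1 of 3 marrow arrays above background their falls from marrow to 0 arrays cannot be read. With 0 AMD3100 arrays above background Amacr was at least 2.49-fold higher after G-CSF than after AMD3100 (fitted 3.57, adjusted p = 0.000348), and with 0 G-CSF arrays Gfra2 was at least 4.46-fold lower (fitted -4.29, adjusted p = 0.000761). Of the lists, lymphoid priming genes stood lower after G-CSF than after AMD3100 (median -1.24, adjusted p = 0.000137, adjusted p = 0.121 with an estimated correlation) and than after CWHM-823+tGro-b (median -0.96, adjusted p = 2.58e-10, adjusted p = 0.0136 with an estimated correlation). Oxidative phosphorylation genes stood higher than after AMD3100 both with G-CSF (median 0.95, adjusted p = 2.96e-12, adjusted p = 0.216 with an estimated correlation) and with CWHM-823+tGro-b (median 0.61, adjusted p = 2.65e-10, adjusted p = 0.317 with an estimated correlation). Calls of these lists against marrow were lost too: with an estimated correlation lymphoid priming had adjusted p = 0.140 after G-CSF, and oxidative phosphorylation 0.0991 after G-CSF, 0.632 after AMD3100 and 0.288 after CWHM-823+tGro-b. With the preset one, lymphoid priming after G-CSF was lost without G-CSF array 2 (0.0598), and oxidative phosphorylation after AMD3100 without marrow array 3 (0.127) or AMD3100 array 2 (0.0960).

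A total of 7390 genes differed between the G-CSF and AMD3100 groups. The tables argue against different signal distributions as the whole of it, since 5921 genes passed with quantile normalization, 5177 of them among the 7390 with the same sign. They also argue against probe GC content, as 13605 passed after its trend was removed in the blocked fit, against 14904 without that correction. RNA yield or amplification cannot be told apart from the group, because the AMD3100 array had the lowest 75th percentile of signal on 3 of 3 slides. The treatment itself, 5 days against 1 hour, stays open and untested.

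Immediate early genes stood higher in every blood group than in marrow, after AMD3100 with adjusted p = 0.0792 with an estimated correlation. Neutrophils in the gate, which lineage depletion and the Kit gate would remove, stay open: the lowest median of 7 abundant neutrophil genes was -1.48, with G-CSF, but it rested on the slide of marrow array 3 (-0.46, -0.12 and -4.14 on the slides). Their medians were 0.78, 0.62 and -3.02 after AMD3100 and -0.03, 0.36 and -3.76 after CWHM-823+tGro-b, and on marrow array 3 read 2.01 log2 units over its 75th percentile. With 0 arrays of blood of untreated mice, handling cannot be told apart from tissue or treatment. One effect common to all blood would leave its groups alike. Against AMD3100, the list's median was 0.66 after CWHM-823+tGro-b (0.46, 0.72 and 0.79 on the slides, adjusted p = 0.317 with an estimated correlation). After G-CSF it was 0.16 (-0.10, 0.08 and 0.50), so that stays open.

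Globin genes stood higher after CWHM-823+tGro-b than in marrow, with Hba-a1 at 4.46 ± 0.34. Red cell RNA, which red cell depletion and the gate would remove, was tested on 10 other red cell genes, whose median was 0.0459 (0.33, -0.25 and 0.27 on the slides). Erythroid progenitors were tested on 6 genes, with a median of -0.0319 (0.59, -0.13 and -0.99). The signs differed between slides, so neither can be told apart from a change in the LSK cells. Against AMD3100 both sets stood higher on every slide, with medians of 0.61 and 0.91.

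For the splits of 6 arrays into 3 and 3, 10 are too few for a share under 0.05. The real split was the only 1 as large in each comparison: 413 genes against at most 0 for G-CSF and marrow, 338 genes against at most 0 for AMD3100 and marrow, 88 genes against at most 1 for CWHM-823+tGro-b and marrow, 7390 genes against at most 0 for G-CSF and AMD3100, 149 genes against at most 5 for G-CSF and CWHM-823+tGro-b and 35 genes against at most 1 for CWHM-823+tGro-b and AMD3100. Of the 4 splits that part all 3 same-numbered pairs, those other than the real one gave 0 genes in every comparison; the rest part fewer pairs. For the mean of the blood groups, 2 of 100 splits, the real one included, gave as many genes as the real 183. The highest other, 267, set the 3 G-CSF arrays against the other 9. These splits ignore the slides. Of all 64 splits with 1 array of each slide in the set of 3, 3 (the real one included) gave as many. With groups intact, AMD3100 against the rest gave 3494, G-CSF 1702 and CWHM-823+tGro-b 44, so 183 is not unusual for a group. For the F-test, 1 of 100 splits gave as many as the real 2832 genes (highest other 2531). Within slides it was 1 of 36 (highest other 124). Mixed splits put group differences into the spread, so chance stays open for both counts.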

How the results depend on the processing

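Quantile normalization and the GC correction, each joined with the slide block, were the tests added once the gene counts were known. Counts of genes that stayed within 1.5 times are left out below, which includes every count with the trend and robust prior and with a fold change of at least 2. With the slide as a block, 4646 for G-CSF against marrow, 3222 for AMD3100 against marrow, 257 for CWHM-823+tGro-b against marrow, 14904 for G-CSF against AMD3100, 523 for G-CSF against CWHM-823+tGro-b, 4010 for CWHM-823+tGro-b against AMD3100, 669 for the mean of the blood groups and 12714 for the F-test passed. Joined with quantile normalization these were 2601, 4306, 266, 12378, 365, 4418, 667 and 10187 in the same order, and with the GC correction 4518, 2398, 252, 13605, 565, 3126, 658 and 11121. The block takes differences between slides out of the spread at a cost in degrees of freedom. With only the groups compared, fewer arrays estimate the spread, and the counts were 231 for G-CSF against marrow, 142 for AMD3100 against marrow, 3873 for G-CSF against AMD3100, 47 for G-CSF against CWHM-823+tGro-b, 11 for CWHM-823+tGro-b against AMD3100 and 678 for the F-test. Quantile normalization gave 743 for AMD3100 against marrow and 108 for CWHM-823+tGro-b against AMD3100, normexp 170 for AMD3100 against marrow and 9 for CWHM-823+tGro-b against AMD3100, and the authors' values 267 for G-CSF against marrow, 547 for AMD3100 against marrow, 99 for G-CSF against CWHM-823+tGro-b and 8 for CWHM-823+tGro-b against AMD3100. No filter on dim probes gave 172 for AMD3100 against marrow and 1687 for the F-test, only probes above background on all arrays 5 for CWHM-823+tGro-b against AMD3100, and every probe tested 60 for CWHM-823+tGro-b against AMD3100. The cause of these moves was not tested. Leaving out 1 array gave ranges of 186 to 743 for G-CSF against marrow, 66 to 322 for AMD3100 against marrow, 53 to 86 for CWHM-823+tGro-b against marrow, 1470 to 10240 for G-CSF against AMD3100, 71 to 184 for G-CSF against CWHM-823+tGro-b, 11 to 72 for CWHM-823+tGro-b against AMD3100, 90 to 167 for the mean of the blood groups and 258 to 5392 for the F-test, and 80 to 89 lists; a group left with fewer arrays is then assumed to vary like the others. Of the 85 list calls, 17 remained in number with an estimated correlation. The r across genes for G-CSF and AMD3100 turned from -0.0635 to 0.00666 with quantile normalization, a cause not tested, and ran without single arrays from -0.179 to 0.0680; the ranges of the other two were 0.377 to 0.664 and 0.155 to 0.489. Of 262 gene results in the text, 218 passed; calls were lost for 13 with quantile normalization, 30 with normexp, 13 in the authors' table, 53 with only the groups compared, 4 with the mean of a gene's probes and 81 without some 1 array, and 0 results reversed while passing. The block changed 3 gene calls, all gained, and no call of a named gene or list other than those printed. Of 96 list results, 85 passed, and calls were lost for 3 with quantile normalization, 2 with normexp, 7 in the authors' table, 5 with the block, 30 with fry, 68 with an estimated correlation and 18 without some 1 array. The results whose direction reversed had not passed, and the cause was not tested. These were the monocyte and macrophage list after G-CSF (adjusted p 0.805 with fry, 0.522 to 0.949 without 1 array) and the NK cell list (0.991 with the block, 0.515 in the authors' table, 0.403 to 0.929 without 1 array). After AMD3100 against marrow, the Csf3r probe read -0.28 with quantile normalization and -0.29 in the authors' table, and Ly6a -0.00338 and -0.00273. With the mean of a gene's probes Itgb1 was at 0.0830 there, and Itga4 at 0.17 after G-CSF and 0.11 for the mean of the blood groups. Leaving out 1 array, the log2 fold changes ranged as follows: Csf3r -0.0172 to 0.17, Itgb1 -0.12 to 0.14, Ly6a -0.26 to 0.29 for AMD3100 against marrow, Cxcr2 -0.37 to 0.00395, Itga4 -0.11 to 0.34, Kit -0.16 to 0.13 for CWHM-823+tGro-b against marrow, Ly6a -0.0453 to 0.52 for CWHM-823+tGro-b against AMD3100, Itga4 -0.23 to 0.12 for G-CSF against marrow, Cxcr2 -0.0119 to 0.30, Itga4 -0.000285 to 0.43, Kit -0.0480 to 0.15 for G-CSF against AMD3100, Cxcr4 -0.31 to 0.0801, Itga4 -0.40 to 0.0552 for G-CSF against CWHM-823+tGro-b and Itga4 -0.15 to 0.0363 for the mean of the blood groups. Signal limits the reading of dim genes: 70.7 to 83.3% of probes were above background on an array, and a fold against a group without signal is only a bound.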

Other observations

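The genes of this part were chosen after their values were seen, and no test of an explanation was run on them. Cd69, a surface protein that holds back lymphocyte exit from tissue, stood among the genes that rose in blood LSK cells in each comparison with marrow, by 4.02 ± 0.35, adjusted p = 0.000107 after G-CSF, 4.15 ± 0.35, adjusted p = 0.000288 after AMD3100 and 4.36 ± 0.35, adjusted p = 8.34e-05 after CWHM-823+tGro-b (n = 3 per group). It was above background on 2 of the 3 marrow arrays. S100a10, a partner of annexin A2 at the plasma membrane, rose by 3.50 ± 0.26, adjusted p = 3.29e-05, 2.14 ± 0.26, adjusted p = 0.00284 and 2.64 ± 0.26, adjusted p = 0.000305 in the same order. Both passed in all 3 comparisons without any 1 array.

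The globin genes also stood apart after G-CSF. Hba-a1 was 6.52-fold higher than after AMD3100 (2.71 ± 0.34, adjusted p = 0.00224), by 2.69, 2.55 and 2.88 on the slides. Hbb-bt was at least 4.81-fold higher after G-CSF than in marrow (adjusted p = 0.000709) and at least 3.47-fold higher than after AMD3100 (adjusted p = 0.00447). The 6 erythroid progenitor genes had a median of -1.04 after G-CSF (-0.92, -0.81 and -1.39 on the slides) and the 10 red cell genes -0.16 (-0.21, -0.21 and 0.02).

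Of 4724 genes with several probes, 30 had probes that passed in opposite directions between G-CSF and AMD3100, and 0 did in the other comparisons.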
